A study of Sinorhizobium meliloti 1021 with 20 samples.

How the data were processed

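Total RNA of the nitrogen-fixing soil bacterium Sinorhizobium meliloti 1021 was measured on 20 single-colour expression arrays with a Cy3 label, 4 in each of 5 groups. The groups were wild type kept at 25 °C (unstressed wild type), wild type after 10 min and after 40 min at 37 °C, and an rpoH1 rpoH2 double mutant after 10 min and after 40 min at 37 °C. Per the labels' protocols, cells grew at 25 °C in LB/MC medium to an optical density of 0.3 at 660 nm, RNA was purified and treated with DNase, and each array holds RNA of its own culture. An unstressed mutant was not analysed here.

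The deposited values are linear intensities, 1 per gene ID and array, made by the authors with RMA, per the file headers and the submitters' processing notes. RMA corrects the background, normalises between arrays and combines the probes of a gene. Per the series' design text, a gene had 4 probes of 60 bases, each spotted 2 times, and in the files 6189 of the 6193 IDs had 8 spots. The RMA version, the arrays that entered 1 RMA run and a genome build are not given in the sources used here. The design text counts 6197 genes, and the files hold 6193 IDs with a value on every array. The table of the whole series held the same values as the files of the single arrays.

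Intensities were put on the log2 scale. The sorted values of the 20 arrays differed by up to 0.47 on that scale at the same rank, so the arrays were quantile normalised together before the tests, by a rule written before the data were examined. No ID was left out. The barcodes of the chips fall into 4 series, named array series A to D here, which are spread unevenly over the groups, and what sets the series apart is not given in the sources used here. Series D held 9 arrays and all groups, 2 arrays of each except 1 of wild type at 40 min. Series A held 1 array of unstressed wild type, 2 of wild type at 40 min and 2 of the mutant at 40 min. Series B held 1 array each of unstressed wild type, wild type at 40 min and the mutant at 10 min. Series C held 2 arrays of wild type and 1 of the mutant at 10 min.

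Group differences were tested with limma 3.58.1 in R 4.3.3. A linear model (lmFit, eBayes) was fitted to all 20 arrays with a mean per group and the array series as a fixed block, which left 12 residual degrees of freedom. Fold changes and log2 changes with an SE are adjusted for the array series, so they can depart from the difference of the plain group means printed beside them, by up to 0.653 (log2) among the 25 changes of named IDs and by over 1.5-fold in 1. Tests were two-sided, and a change was called at a Benjamini-Hochberg adjusted p under 0.05 over the 6193 IDs. All adjusted p of single IDs below are from this limma model. The 9 comparisons were the early (10 min) and late (40 min) heat responses of wild type against unstressed wild type, the early and late mutant differences from wild type at the same time, the 40 min against 10 min difference in wild type and in the mutant, the interaction (late less early mutant difference), and the mutant at each time against unstressed wild type. The labels number the replicates of each group 1 to 4. The deviations from the group means of same-numbered arrays correlated at 0.666, 0.576, 0.869 and 0.759 in the late mutant difference and at 0.611, 0.661, 0.875 and 0.186 in the wild-type time comparison, so the numbers were taken to pair the arrays there. In every other comparison of 2 groups at least 1 pair correlated below 0.1. The pairing comes from these values, not from the labels, and the numbers partly follow the array series. The series was not removed before these correlations, so they may reflect the series rather than paired cultures. On simulated data with the spread of these arrays, in which 200 of 6193 IDs were changed, the early response test found 35% of 2-fold and 88.2% of 4-fold changes with a mean of 1.2 false calls over 5 draws. The early mutant difference test found 38.8% and 88% with 0.4 false calls. The number of arrays limits the precision, and the files used here give no measure of signal against background.

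The gene table given for this work belongs to another species, and 0 of the 6193 IDs matched any of its 6946 entries. The files do not pair the IDs with symbols. IDs are therefore printed without gene names, and the levels of the disrupted genes, their neighbours and the 29 gene lists fixed on symbols were not analysed here, since 0 lists had a measured member. The rule for named IDs took IDs past the threshold with the highest and lowest log2 fold changes whose groups did not overlap (for the interaction, past the threshold only). Its condition on a symbol was dropped and its length set to 2 IDs each way after the missing symbols were seen.

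By the annotation convention of this genome, IDs that start with SMa lie on the megaplasmid pSymA (1294 IDs), with SMb on the megaplasmid pSymB (1563) and with SMc on the chromosome (3336). Calls per prefix were compared with Fisher's exact test, and the shift of each prefix with camera at a preset correlation of 0.01 and again with an estimated correlation. Overlaps of comparisons that share arrays are given with the number for independent lists, with simulated unchanged groups (100 draws), and, where made, with the shared arrays split into 2 pairs. The pairs were replicates 1 and 2 against 3 and 4 of unstressed wild type, and 1 and 3 against 2 and 4 of heated wild type. The most similar replicates (2 and 3 of unstressed wild type, 1 and 2 of wild type at 10 min) fall in opposite pairs. Noise that such arrays share is not removed by the split. Unchanged groups gave any call in at most 4 of 100 draws of a comparison, so their overlap of 0 says little about lists that hold calls. A draw with calls could hold many, up to 2376 in the late response and 1765 in the early mutant difference. In the early response the highest count was 0. With 1 response kept and the other groups set to no change, a simulation chosen after seeing the data, the unchanged list held calls in 0 or 1 of 100 draws, so it says little too.

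Alternatives written before the data were examined were the table of the whole series, median centring without the quantile step, values as deposited, leaving out dim IDs, no array series block, the slide as a random block, array series D alone, a replicate block, only the groups compared, trend and robust eBayes, array weights, a 2-fold minimum and leaving out each array in turn. Chosen after seeing the data were blocks from the first principal component, the SMa median as a covariate, a replicate block in place of the array series, array series A alone, leaving out 3 arrays that stand apart, leaving out 1 array of each of the 3 most similar pairs, and permutation tests of the prefix medians per array. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.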

Results

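The series measured how the transcriptome of Sinorhizobium meliloti 1021 changes after a shift from 25 to 37 °C, and how much of that change needs rpoH1 and rpoH2. These encode heat shock sigma factors, the subunits that direct RNA polymerase to heat shock genes. The 20 arrays came from 5 groups of 4 separate cultures. Their median intensity lay between 514 and 608, with 6193 IDs on each. The first principal component held 59.9% of the variance and parted array series A and C from B and D, and the second held 11.8%. The most similar pair of arrays was replicates 2 and 3 of unstressed wild type, whose log2 values differed with an SD of 0.175 (r = 0.995 across IDs). It was followed by replicates 2 and 3 of the mutant at 10 min (SD 0.191) and replicates 1 and 2 of wild type at 10 min (SD 0.241). The labels describe these as separate cultures, and they were counted as such. Whether a pair holds 1 RNA on 2 arrays, which would put n below 4, is open. With 1 array of each pair left out, the early response had 131 IDs, the late one 105 and the mutant at 10 min against unstressed wild type 29.

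The early heat response shows what changed within 10 min in wild type. SMb21567 rose 44.8-fold (log2 5.49 ± 0.33 SE, adjusted p = 2.55e-08), from a log2 level of 9.62 ± 0.25 (SD, n = 4) in unstressed cells to 15.05 ± 0.075 (SD, n = 4). SMc04040 rose 34.3-fold (log2 5.10 ± 0.33 SE, adjusted p = 3.14e-08), from 9.85 ± 0.75 to 14.87 ± 0.76 (SD, n = 4 each). SMc01428 fell 24-fold with the series block (log2 -4.59 ± 0.36 SE, adjusted p = 3.33e-07), and 15.3-fold between the plain group means, from 14.28 ± 0.67 to 10.34 ± 1.20 (SD, n = 4 each). SMc04319 fell 16.5-fold (log2 -4.04 ± 0.32 SE, adjusted p = 3.33e-07), from 12.19 ± 0.28 to 8.16 ± 0.22 (SD, n = 4 each). For each of these IDs, all 4 heated arrays lay on the same side of all 4 unstressed ones. In all, 453 IDs changed, of which 160 were higher (median log2 1.20) and 293 lower (median log2 -1.51). Of these, 115 of the higher and 279 of the lower IDs moved at least 2-fold. Within array series D, with 2 arrays of each group, SMb21567, SMc04040, SMc01428 and SMc04319 differed by 5.56, 4.79, -4.65 and -4.23 (log2). In that series alone 9 IDs passed. The count was 103 without the series block (68 higher, 35 lower), 1022 with these groups alone and 1650 with array weights. Higher IDs also outnumbered lower ones with a replicate block in place of the series (135 and 82) and without replicate 3 of wild type at 10 min (69 and 56), so which direction prevailed depended on the fit. Leaving out 1 array moved it between 86 (without replicate 4 of wild type at 10 min) and 729 (without replicate 4 of the mutant at 10 min).

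The late heat response compares wild type after 40 min with unstressed wild type. SMb21567 stood 51.7-fold above its unstressed level (log2 5.69 ± 0.29 SE, adjusted p = 1.15e-09), at 15.41 ± 0.37 (SD, n = 4). SMb21566 rose 37.8-fold (log2 5.24 ± 0.27 SE, adjusted p = 1.15e-09), from 10.32 ± 0.29 to 15.59 ± 0.235 (SD, n = 4 each). SMc01428 was 20.6-fold lower (log2 -4.37 ± 0.31 SE, adjusted p = 8.73e-08), at 10.11 ± 0.73 (SD, n = 4). SMc04318 fell 17.2-fold (log2 -4.10 ± 0.29 SE, adjusted p = 8.73e-08), from 12.38 ± 0.41 to 8.38 ± 0.51 (SD, n = 4 each). Of the 402 IDs that changed, 211 were higher and 191 lower, with 145 and 150 moving at least 2-fold. The early and late responses shared 84 higher and 116 lower IDs, against 5.45 and 9.04 for independent lists. Both use the unstressed arrays. Simulated unchanged groups, which seldom give calls, shared 0 IDs in each of 100 draws. With those arrays split into 2 pairs, the responses shared 14 and 16 higher and 11 and 16 lower IDs. In heated wild type SMb21567 (14.86 to 15.69) and SMb21566 (15.25 to 15.78) lay towards the highest intensity of each array (54864 to 63186 before the log). SMc04040 came near it on some arrays only, with a range of 11.92 to 15.56. Saturation is not measured in the files used here, so the folds of these IDs that involve heated wild type may be understated. Within series A, B and D, SMb21567 was higher by 5.56, 6.10 and 5.41 (log2) and SMc01428 lower, at -4.83, -4.88 and -3.41, with 1 or 2 arrays of each group per series. The count was 87 without the series block (58 higher, 29 lower), 0 in series D alone (1 array against 2), 74 in series A alone (56 and 18, 2 against 1) and 1950 with principal component bands as the block. It ranged from 65 (without replicate 1 of unstressed wild type) to 611 (252 higher and 359 lower, without replicate 4 of wild type at 40 min), so the balance of directions depended on the fit.

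The early mutant difference compares the strains after 10 min at 37 °C. Without an unstressed mutant it also holds any difference the strains had before heat. SMc04040 was 48.5-fold lower in the mutant (log2 -5.60 ± 0.30 SE, adjusted p = 3.37e-09), at 9.16 ± 0.41 (SD, n = 4), and did not differ detectably from unstressed wild type (log2 -0.50 ± 0.30 SE, adjusted p = 0.409). SMb21295 was 11.3-fold lower (log2 -3.49 ± 0.35 SE, adjusted p = 1.73e-05), at 8.65 ± 0.71 against 12.54 ± 1.36 in wild type (SD, n = 4 each). SMc03873 was the 1 ID higher in the mutant, 4.41-fold (log2 2.14 ± 0.41 SE, adjusted p = 0.0166), at 9.59 ± 1.17 against 7.69 ± 0.25 (SD, n = 4 each). The IDs of the disrupted genes were not identified here, so whether SMc03873 is one of them is open. The other 25 of the 26 IDs called were lower, and 20 of these 25 were among the 160 that rose early in wild type. These 20 IDs had a median early response of log2 2.25 in wild type. In the mutant against unstressed wild type their median was 0.030 (-1.29 to 2.16), with 10 above and 10 below 0. The same arrays picked these IDs, so this median is no independent measure of a loss of induction. Independent lists would share 0.646 IDs. The lists have the arrays of wild type at 10 min in common. Simulated unchanged groups, which seldom give calls, shared 0 IDs in each of 100 draws. A simulated mutant equal to heated wild type gave 20 or more shared IDs in 4 of 100 draws (median 0, mean 17.6, highest 829). With those arrays split into 2 pairs, 8 of 13 and 12 of 43 IDs found higher with 1 pair were lower in the mutant against the other pair. Within series C and D, SMc04040 differed by -5.89 and -5.32 (log2), SMb21295 by -4.00 and -2.98 and SMc03873 by 2.82 and 1.95. The count was 7 with these groups alone, 1 in series D alone, 14 without replicate 1 of the mutant at 10 min, 104 with array weights and 93 with bands. The 20 shared IDs became 7 with these groups alone, 1 in series D alone, 70 with array weights and 58 with bands, 11 without replicate 4 of wild type at 10 min and 13 without replicate 1 of the mutant at 10 min (up to 28 without another array). SMc03873 lost its call in 8 of 37 alternatives, the fit without the series block among them.

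**Figure D1:**
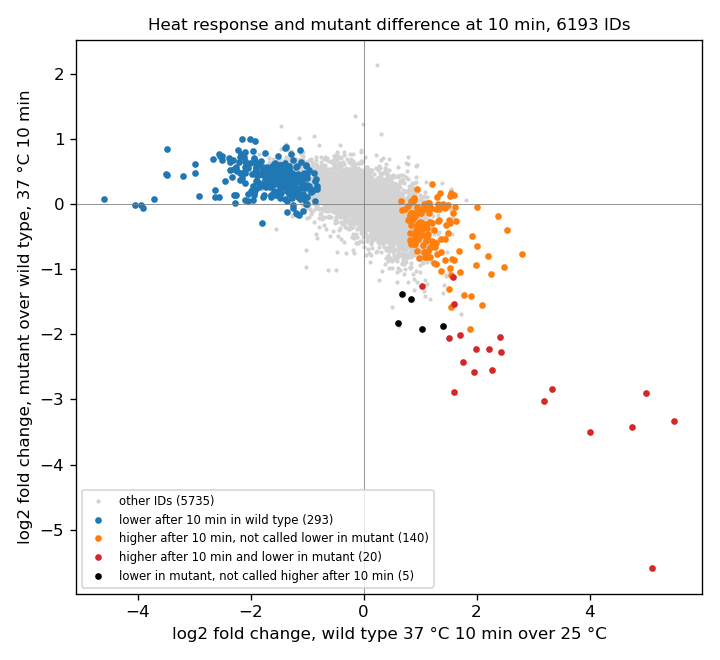
Log2 fold change of 6193 IDs between wild type after 10 min at 37 °C and unstressed wild type (x axis) and between the mutant and wild type after 10 min (y axis), from groups of 4 arrays. The 20 IDs that were higher after heat and lower in the mutant lie at the lower right, the 293 IDs that fell lie at the left, 282 of them above 0 on the y axis (median 0.39; both axes use the same wild-type arrays at 10 min).

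The late mutant difference compares the strains after 40 min. SMc04040 was 22.3-fold lower in the mutant (log2 -4.48 ± 0.29 SE, adjusted p = 8.8e-08), at 9.31 ± 0.91 against 13.95 ± 1.44 (SD, n = 4 each). SMb21567 was 10.8-fold lower (log2 -3.44 ± 0.29 SE, adjusted p = 3.04e-06), at 11.94 ± 0.43 (SD, n = 4). It still stood 4.76-fold above unstressed wild type (log2 2.25 ± 0.29 SE, adjusted p = 0.000242). SMc03873 was 5.35-fold higher (log2 2.42 ± 0.40 SE, adjusted p = 0.005), at 10.05 ± 0.90 against 7.61 ± 0.48 (SD, n = 4 each). SMb21653 was 3.20-fold higher (log2 1.68 ± 0.35 SE, adjusted p = 0.0462), at 10.14 ± 0.52 against 8.59 ± 0.81 (SD, n = 4 each). The remaining 18 of 20 called IDs were lower. Of these 18, 15 were also lower at 10 min, against 0.0727 for independent lists (exact hypergeometric test, one-sided, p = 4.67e-36, across IDs, which are not independent replicates). The 2 mutant differences share no arrays, but both come from 1 fit with the same spread per ID and the same array series terms. The lists are thus not fully independent. The 15 IDs had median responses of log2 2.28 early and 1.79 late in wild type. Against unstressed wild type their medians in the mutant were -0.24 and -0.19, on the arrays that also picked them. The late lists shared 14 IDs that were higher in wild type after heat and lower in the mutant, against 0.613 for independent lists. Unchanged groups, with few calls, gave 0 in each of 100 draws. A mutant equal to heated wild type gave 14 or more in 2 of 100 draws (median 0, mean 3.55, highest 216). With the arrays of wild type at 40 min split into 2 pairs, 9 and 8 IDs were shared. Within series A and D, SMc04040 differed by -4.86 and -3.39 (log2), SMb21567 by -3.41 and -3.11, SMc03873 by 2.80 and 2.30 and SMb21653 by 2.39 and 1.13. The count was 12 without the series block, 0 in series D alone, 1 in series A alone, 31 with array weights, 65 with bands and 105 with the SMa median as a covariate. The 14 shared IDs became 8, 0 and 1 in the first 3 of these fits and 31 and 37 in the last 2. SMb21653 lost its call in 22 of 38 alternatives, and with a replicate block beside the series it stood at log2 1.70 (adjusted p = 0.0739).

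The wild-type time comparison depended on the fit: it had 1 call in the limma model, 88 with these groups alone, 69 with the SMa median as a covariate and 536 with principal component bands as the block (30 in the mutant). SMc02433 was the 1 ID in the limma model. Between 10 and 40 min it fell 7.24-fold with the series block (log2 -2.86 ± 0.39 SE, adjusted p = 0.00701), and 5.60-fold between the plain group means, from 13.98 ± 0.22 to 11.50 ± 0.69 (SD, n = 4 each). This followed a 27-fold early rise over its unstressed level of 9.41 ± 0.19 (SD, n = 4). In the mutant its level was 10.57 ± 0.58 at 10 min and 11.15 ± 0.69 at 40 min (SD, n = 4 each). The mutant difference of SMc02433 was thus log2 -3.42 ± 0.33 SE at 10 min (adjusted p = 1.2e-05) and -0.33 ± 0.32 SE at 40 min (adjusted p = 0.946). The interaction, 3.09 ± 0.47 SE, passed the limma test (adjusted p = 0.0289), as it did for no other ID. The mutant showed 0 limma calls between 10 and 40 min. At an unadjusted p under 0.05, the wild-type time comparison had 532 IDs (283 higher, 249 lower), that in the mutant 208 (104 and 104) and the interaction 293 (160 and 133). Within series D, the series with both times, SMc02433 fell by 3.62 (log2) in wild type, with 1 array at 40 min and 2 at 10 min. Its time call was lost in 4 of 37 alternatives, when replicate 3 or 4 of wild type at 10 min or replicate 4 of wild type at 40 min was left out and in series D alone. Its interaction was lost in 20 of 37, the fit without the series block among them, with a log2 value between 2.77 and 3.80 where it was lost.

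**Figure D2:**
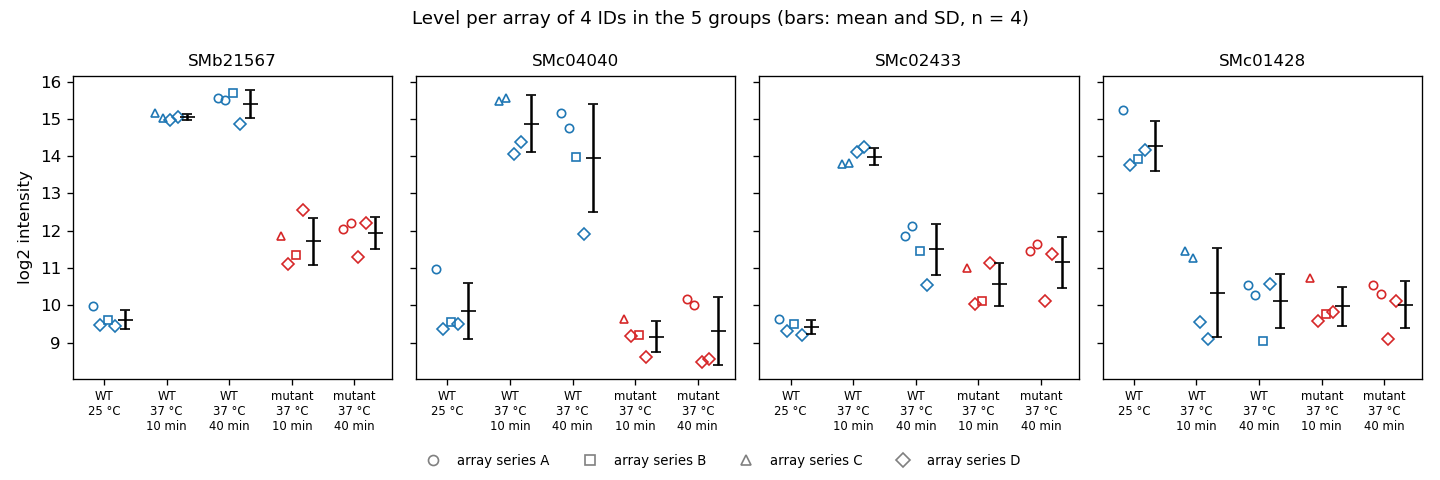
Log2 intensity of SMb21567, SMc04040, SMc02433 and SMc01428 on each of the 20 arrays (points, shaped by array series), with the mean and SD of each group of 4 (bars). In the mutant, SMc04040 lies at 9.16 and 9.31 against 9.85 in unstressed wild type, SMb21567 reaches 11.71 and 11.94, and SMc01428 lies below unstressed wild type in all 4 heated groups.

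The mutant at 10 min was set against unstressed wild type to see which IDs moved without rpoH1 and rpoH2. With no unstressed mutant, heat and genotype change together in this comparison. SMc01428 was 22.6-fold lower (log2 -4.50 ± 0.32 SE, adjusted p = 2.39e-07), at 9.97 ± 0.51 (SD, n = 4). SMc04319 was 16.6-fold lower (log2 -4.06 ± 0.28 SE, adjusted p = 2.39e-07), at 8.18 ± 0.41 (SD, n = 4). SMc03873 was 5.23-fold higher (log2 2.39 ± 0.41 SE, adjusted p = 0.00465), and whether it belongs to a disrupted gene is open. SMc01504 was 4.61-fold higher (log2 2.20 ± 0.475 SE, adjusted p = 0.019), at 12.14 ± 0.33 against 10.12 ± 0.64 (SD, n = 4 each). SMc01504 moved by a like amount in wild type (log2 2.38 ± 0.53 SE, adjusted p = 0.0149). Its call in the mutant was lost in 5 of 37 alternatives, the fit without the series block among them, and that of SMc03873 in 2. Of 196 IDs that changed, 75 were higher and 121 lower. They shared 51 higher and 111 lower IDs with the early response of wild type, against 1.94 and 5.72 for independent lists and 0 in each of 100 draws of unchanged groups, which seldom give calls. With the unstressed arrays split into 2 pairs, they shared 6 and 6 higher and 14 and 13 lower IDs. All 293 IDs that fell early in wild type had a negative value in the mutant (median log2 -1.14), which shares the unstressed arrays. With those arrays split, 57 of 57 and 30 of 30 IDs that fell with 1 pair were negative in the mutant against the other, where 40% and 49.1% of all IDs were. Of those that rose with 1 pair, 6 of 41 and 4 of 20 were negative in the mutant against the other. Replicates 2 and 3 of unstressed wild type, the most similar arrays, lay in opposite pairs, so noise they may share was not removed. Within series B and D, SMc01428 differed by -4.14 and -4.28 (log2) and SMc03873 by 1.70 and 2.28. The count was 30 without the series block (15 higher, 15 lower), 4 in series D alone, 5 with these groups alone, 1716 with array weights and 1205 with bands. It ranged from 69 (without replicate 3 of the mutant at 10 min) to 580 (without replicate 4 of the mutant at 10 min).

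After 40 min, the mutant differed from unstressed wild type in 458 IDs, 240 higher and 218 lower, again with heat and genotype changing together. SMc04276 was 7.05-fold higher (log2 2.82 ± 0.37 SE, adjusted p = 0.000255), at 11.82 ± 0.71 against 8.94 ± 0.46 (SD, n = 4 each). SMc03873 was 6.40-fold higher (log2 2.68 ± 0.40 SE, adjusted p = 0.000785), at 10.05 ± 0.90 against 7.17 ± 0.075 (SD, n = 4 each). SMc04276 also rose in wild type by 40 min (5.77-fold, adjusted p = 0.00056), whereas SMc03873 did not pass there (log2 0.26 ± 0.40 SE, adjusted p = 0.785). SMc01428 was 23.1-fold lower (log2 -4.53 ± 0.32 SE) and SMc04318 17.8-fold lower (log2 -4.16 ± 0.30 SE), both at an adjusted p of 1.33e-07. The mutant and wild type at 40 min shared 114 higher and 117 lower IDs, against 8.18 and 6.72 for independent lists and 0 in each of 100 draws of unchanged groups, which seldom give calls. With the unstressed arrays split into 2 pairs, they shared 8 and 12 higher and 12 and 11 lower IDs, against 0.133 and 0.488 and 0.156 and 0.226 for independent lists. Within series A and D, SMc04276 differed by 4.06 and 2.11 (log2) and SMc01428 by -4.83 and -4.36. The count was 128 without the series block (78 higher, 50 lower), 129 with these groups alone (60 and 69), 4 in series D alone, 193 in series A alone (122 and 71) and 1665 with bands. It ranged from 74 (30 higher and 44 lower, without replicate 1 of unstressed wild type) to 559, and the balance of directions turned with the fit.

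In the limma model the IDs that fell after heat lay mostly on the chromosome. In the early response 261 of 3336 SMc IDs (7.82%) fell, against 13 of 1294 SMa IDs (1%) and 19 of 1563 SMb IDs (1.22%). The odds ratio was 7.49 for SMc IDs against the rest (Fisher's exact test, two-sided, adjusted p = 9.68e-39 over 24 tests, across IDs, which are not independent replicates). In the late response 165 SMc IDs (4.95%), 11 SMa IDs (0.85%) and 15 SMb IDs (0.96%) fell, an odds ratio of 5.66 (Fisher's exact test, adjusted p = 4.52e-21). These counts per prefix are from the limma model only. The Fisher tests took no account of the level of the IDs or of the shifts of whole prefixes given below. Without the series block 35 IDs fell early and 29 late, and their prefixes were not tested. Higher IDs showed no such tilt in either response (lowest adjusted p = 0.192, Fisher's exact test). Of the 25 IDs lower in the mutant at 10 min, 18 were SMc, 7 SMb and 0 SMa (Fisher's exact test for SMa, adjusted p = 0.0173). At 40 min 0 SMa IDs were lower too, which did not pass (Fisher's exact test, adjusted p = 0.061). As whole sets, SMb IDs had a median early response of log2 0.21 (camera adjusted p = 3.19e-05 with the preset correlation, adjusted p = 0.0143 with an estimated correlation). This call was lost without the series block (median 0.071, camera adjusted p = 0.0933) and with a replicate block in its place (camera adjusted p = 0.0649). The early medians of SMa IDs (0.28) and SMc IDs (-0.12), the late ones of SMa (0.13), SMb (0.10) and SMc IDs (-0.10) and the early mutant differences of SMa (-0.15) and SMc IDs (0.10) passed with the preset correlation. They were lost with the estimated one, at an adjusted p = 0.47 and 0.134, then 0.566, 0.0644 and 0.273, then 0.551 for both. The late mutant difference passed for no prefix in the limma model, and with a replicate block beside the series for SMa (-0.10, camera adjusted p = 0.00197) and SMc IDs (0.068, camera adjusted p = 0.0276). No difference of per-array medians passed an exact permutation test, two-sided, the lowest of 12 p being 0.0571 (SMb IDs, late response) where 0.0286 is the smallest that 4 against 4 arrays allow. The sign for SMa IDs turned with the treatment of the array series: the plain differences of their array medians were -0.21, -0.11, 0.24 and -0.093 (log2) in the early and late responses and mutant differences, against fitted medians of 0.28, 0.13, -0.15 and 0.013. For SMc IDs it turned at 10 min only. Their plain differences were 0.042 (early response) and -0.092 (early mutant difference), against fitted medians of -0.12 and 0.10.

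**Figure D3:**
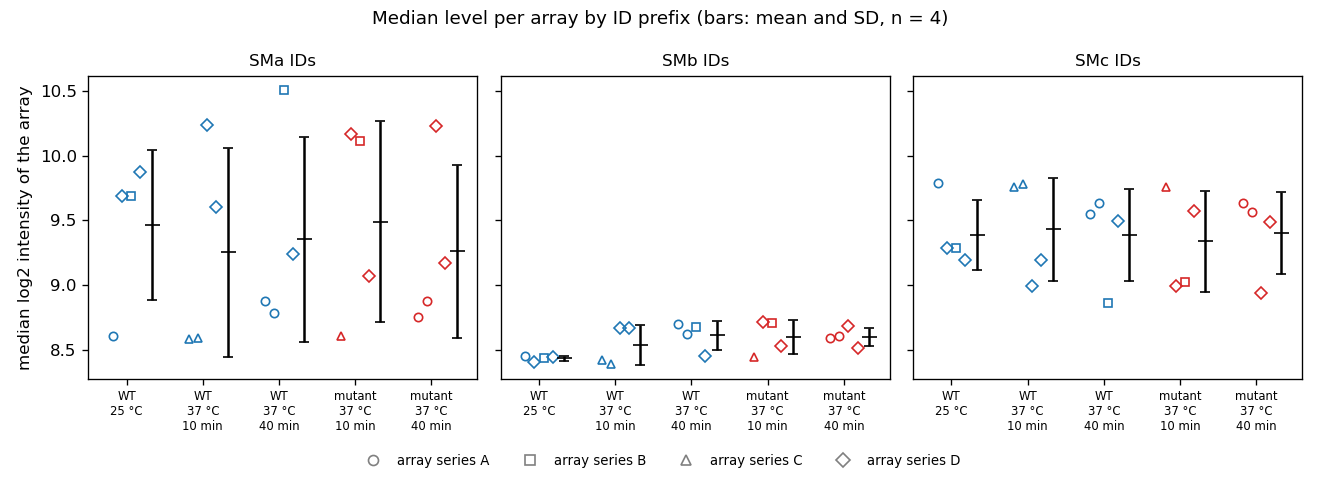
Median log2 intensity of the SMa, SMb and SMc IDs on each of the 20 arrays (points, shaped by array series), with the mean and SD of each group of 4 (bars). SMa medians spread by up to 1.72 within a group and their group means by 0.236, and SMb medians stay between 8.40 and 8.72.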

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

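The tests of explanations in this part were chosen after the results had been seen. Single arrays were looked for that lay far from the other 3 arrays of their group, over 75 groups of 4, where chance alone gives about 5%, and 6 were found. Replicate 1 of unstressed wild type, the 1 array of its group in array series A, accounted for 4 of them. Its SMc04040 level was 10.96 (log2) against 9.37, 9.51 and 9.56 on the other 3 arrays, its SMc01504 level 9.18 against 10.30, 10.48 and 10.52, its SMa median 8.61 and its SMc median 9.79. Replicate 4 of unstressed wild type had an SMc04319 level of 12.6 against 12.02, 12.03 and 12.10. Replicate 3 of the mutant at 40 min had an SMc02433 level of 10.12 against 11.38, 11.45 and 11.64. The mutant difference of SMc02433 was less negative at 40 min than at 10 min by 3.09 (log2), which the limma test of the difference itself passed.

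The SMa median spread over 1.92 (log2) between the 20 arrays, from 8.59 to 8.88 on the 8 arrays of series A and C and from 9.07 to 10.51 on the 12 of series B and D. The experimental groups do not account for it: every group had a range of 1.26 or more, while the group means lay within 0.236. Genomic DNA in the RNA would raise dim IDs of each replicon, yet from series C to series B and D dim SMb IDs rose by a median of 0.258, dim SMa IDs by 1.13 and dim SMc IDs by -0.07. The array series may account for the gap of 0.188 between the 2 sets of series, but not for the spread within series D, where 2 arrays of the mutant at 40 min on 1 slide differed by 1.05. What stays open is a difference between the cultures or RNA preparations that ran with the series, the number of pSymA copies among them, and base composition, none of which was tested for lack of a genome and of DNA measurements.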

How the results depend on the processing

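All alternatives below were planned except those named as chosen after seeing the data, and the test of other splits of the arrays was designed with the results at hand. The 20 IDs and 14 IDs that were higher after heat and lower in the mutant are called the early and late overlaps. Signal over background limits the precision in a way the files used here do not measure. The table of the whole series holds the same values, so its counts could not differ. Median centring, values as deposited, leaving out dim IDs, the slide as a random block, trend and robust eBayes and a 2-fold minimum left every count within 1.5 times. No named ID reversed under any alternative. Series A and D alone hold fewer arrays, and their counts below were lower. The cause of a changed count was not tested.

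Without the series block the counts were 103 (early response), 87 (late response), 12 (late mutant difference), 0 (interaction), 30 and 128 (mutant at 10 and 40 min against unstressed wild type) and 8 (late overlap). In series D alone they were 9, 0, 1 and 0 (early and late responses and mutant differences), 0 (wild-type time comparison), 0 (interaction), 4 and 4 (mutant against unstressed wild type), and 1 and 0 (overlaps). With only the groups compared they were 1022 and 87 (responses), 7 (early mutant difference), 88 (wild-type time comparison), 0 (interaction), 5 and 129 (mutant against unstressed wild type), and 7 and 8 (overlaps). With array weights, a fit that stopped before full convergence, they were 1650 (early response), 104 and 31 (mutant differences), 4 (interaction), 1716 (mutant at 10 min) and 70 (early overlap).

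Chosen after seeing the data, 3 bands of arrays (8, 3 and 9) from the first principal component as the block in place of the series gave 1116 and 1950 (responses), 93 and 65 (mutant differences), 536 and 30 (time comparisons of wild type and mutant) and 2 (interaction). This block gave 1205 and 1665 (mutant against unstressed wild type), and 58 and 31 (overlaps). Bands and series together gave 1051 and 1718 (responses), 64 and 41 (mutant differences), 2 (wild-type time comparison), 1355 and 1555 (mutant against unstressed wild type) and 37 (early overlap). The bands come from the data themselves. The SMa median as a covariate gave 1045 and 1311 (responses), 84 and 105 (mutant differences), 69 (wild-type time comparison) and 3 (interaction). It also gave 977 and 1278 (mutant against unstressed wild type) and 59 and 37 (overlaps). Without the 3 replicate 4 arrays that stand apart (wild type at 40 min and both mutant groups) the counts were 876 and 1599 (responses) and 55 and 58 (mutant differences). They were 962 and 1247 for the mutant against unstressed wild type and 36 and 24 for the overlaps. With 1 array of each of the 3 most similar pairs left out they were 131 and 105 (responses), 0 (interaction), 29 and 213 (mutant against unstressed wild type) and 13 (early overlap). In series A alone they were 74 (late response), 1 (late mutant difference), 193 (mutant at 40 min) and 1 (late overlap).

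In the late mutant difference and the wild-type time comparison the replicate numbers were taken to pair the arrays. A replicate block beside the series gave 22 and 1 calls there, ended the call of SMb21653 and gave SMa and SMc medians of -0.101 and 0.0675 in the late mutant difference. It changed no other call of a named ID or prefix in these 2 comparisons. In the other comparisons the arrays share only a number: over all groups 31 of 40 same-numbered pairs correlated above 0.1, from -0.84 to 0.914, and 11 of 20 arrays correlated best with their own number. There the block gave 345 for the mutant at 10 min and 0 for the interaction, where SMc02433 stood at log2 3.16 (limma adjusted p = 0.156). Chosen after seeing the data, the replicate block in place of the series gave 217 (early response), 41 (early mutant difference), 0 (interaction), 68 (mutant at 10 min) and 34 (early overlap).

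Leaving out 1 array changed the early response count to 220 and 233 (replicates 2 and 3 of unstressed wild type), 125 and 86 (replicates 3 and 4 of wild type at 10 min), 280 and 729 (replicates 3 and 4 of the mutant at 10 min) and 685 (replicate 3 of the mutant at 40 min). The late response changed to 65 and 243 (replicates 1 and 3 of unstressed wild type) and to 176, 223, 186 and 611 (replicates 1 to 4 of wild type at 40 min). The early mutant difference ranged from 14 (replicate 1 of the mutant at 10 min) to 38, and the late one from 14 to 28. The early overlap ranged from 11 (replicate 4 of wild type at 10 min) through 13 (replicate 1 of the mutant at 10 min) to 28, and the late overlap from 11 to 15. The wild-type time comparison ranged from 0 (replicates 3 and 4 of wild type at 10 min, replicate 4 at 40 min) to 2 (replicate 3 at 40 min). The interaction ranged from 0 (14 of the 20 arrays) to 3 (replicate 3 of wild type at 40 min). The mutant at 10 min against unstressed wild type changed to 103, 78 and 77 (replicates 1 to 3 of unstressed wild type), 99 and 106 (replicates 1 and 2 of wild type at 10 min) and 79, 70, 69 and 580 (replicates 1 to 4 of the mutant at 10 min). The mutant at 40 min changed to 74 (replicate 1 of unstressed wild type), 234 and 225 (replicates 1 and 2 of the mutant at 40 min), with 559 the highest.

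Without the series block SMa IDs were at -0.135, -0.0321, 0.168 and -0.0941 (early and late responses, early and late mutant differences), SMb IDs at 0.0713 (early response) and SMc IDs at 0.0321 and -0.0599 (early response, early mutant difference). The replicate block in place of the series gave these values too, and an SMc median of 0.061 in the late mutant difference. In series D alone SMa IDs were at 0.175, -0.487 and 0.448 (early and late responses, late mutant difference), SMb IDs at -0.0174 and 0.14 and SMc IDs at 0.131 and -0.185 (late response, late mutant difference). In the early mutant difference SMa and SMc IDs were at 0.121 and -0.0494 with bands, where SMb IDs were at 0.0676. They were at 0.1 and -0.0201 with bands and series, and at 0.0941 and -0.0248 without the 3 arrays that stand apart. In the late mutant difference SMa IDs were at -0.0941, -0.0829 and -0.106 in these settings, and SMc IDs at 0.061 with bands and 0.0726 without the 3 arrays. With an estimated correlation the medians keep their values, 0.279 and -0.118 (SMa, SMc) in the early response, 0.131, 0.1 and -0.102 (SMa, SMb, SMc) in the late response and -0.152 and 0.0995 (SMa, SMc) in the early mutant difference, and no longer pass. Leaving out 1 array, the SMa medians ranged from 0.0545 to 0.422 (early response), -0.092 to 0.365 (late response), -0.309 to 0.0227 (early mutant difference) and -0.196 to 0.171 (late mutant difference). The SMb median ranged from 0.0778 to 0.164 in the late response. The SMc medians ranged from -0.188 to -0.0382 (late response), 0.0171 to 0.155 (early mutant difference) and -0.0654 to 0.121 (late mutant difference).

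Other splits of the same arrays into 4 against 4 were fitted in the same way. For the early and late responses, the early mutant difference and the mutant at 10 and 40 min against unstressed wild type, the real split gave the highest count (1 of 35 splits each). It gave 453, 402, 26, 196 and 458 calls against 0, 0, 0, 0 and 195 in the highest other, which argues against chance but does not exclude it. A share of 1 of 35 is the smallest these splits allow, and the real split keeps the most similar pairs of arrays together. Other splits mix the groups, so a real difference widens their spread and lowers their counts. For the late mutant difference, 2 of 35 splits gave its 20 calls or more, the other being the 4 series A arrays against those of series B and D with 38. This count does not argue against chance. The same holds for the wild-type time comparison (2 of 35 splits with its 1 call, the other parting series A and C from B and D with 4) and the interaction (7 of 100 splits drawn, real count 1, highest other 1933). The 2 splits with 38 and 4 calls part 0 of the 4 same-numbered pairs. Among the 8 splits that part all 4, too few for a share under 0.05, the highest other count was 0 in both comparisons. For the mutant time comparison, with a real count of 0, the count of splits decides nothing (35 of 35, highest other 1973). The splits with 1973 and 1933 calls point to a structure of the arrays. Both part the arrays of the band of 3 from those of the band of 9, and the split with 1933 calls does so within each time.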

Other observations

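The tests in this part were chosen after the results had been seen. IDs that changed tended to carry neighbouring numbers. Of the 160 IDs that rose early in wild type, 52 were next in number to another of them, of the 293 that fell 151, and of the 25 that were lower in the mutant at 10 min 12. Among 10000 random lists with as many IDs of each prefix, the medians were 8, 40 and 0 and the highest values 24, 69 and 6, so chance is argued against for all 3 lists. SMb21566 and SMb21567 (both far higher after heat) and SMc04318 and SMc04319 (both far lower) are such neighbours. Co-transcription of neighbouring genes is a possible explanation that these data leave open, as an annotation of operons was not used here, and cross-hybridisation between neighbours was not tested either.

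Of the 160 IDs that rose early in wild type, 140 were not called lower in the mutant, with median early changes of log2 1.14 in wild type and 0.728 in the mutant, both against unstressed wild type, and 48 of the 140 were called higher in the mutant too. In 100 simulated draws the mutant was set equal to unstressed wild type. A ratio of these medians as large as the observed 0.638 came in 2 draws (median of draws 0.385). As many such calls came in 2 draws too (median 0, highest 391). With every ID of the mutant left unchanged, draws seldom give calls, so this count says little. The draws also took the fitted heat response as true, so noise of the unstressed arrays held in it did not reach the mutant. Their ratios may thus be too low. A full loss missed by the test, and chance shared through the unstressed arrays, are decided by neither measure. The share above 0 in the mutant, 138 of 140, decides nothing, since all 100 draws gave as large a share. A partial loss stays open too: 121 of 140 were below heated wild type (median log2 -0.358), on the arrays that also picked them. IDs were also picked on 2 replicates of unstressed wild type, wild type at 10 min and the mutant at 10 min. On the other 2 their medians in the early mutant difference lay between -3.07 and -0.444 (5 picks of 1 to 16 IDs, and 1 pick with 0). These picks do not decide it, as their IDs need not be among the 140. The medians of -3.07 and -2.22 lie below -1.92, the lowest value of any of the 140 in the full fit. A genotype difference before heat was not tested, as an unstressed mutant was not analysed here.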
